A study of Homo sapiens with 25 samples.

How the data were processed

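Poly(A)+ RNA of MCF-7 cells was sequenced in 25 libraries. The labels place 12 of them in the knockdown sets, with a control siRNA and 2 siRNAs per target (lncRNA152 and lncRNA67) and 2 replicates each, 12 in cytoplasmic, nuclear or chromatin fractions with or without estradiol, and 1 in an unfractionated group. The fraction libraries were not analysed here. Per the submitters' processing notes, TopHat, Cufflinks 2.0.2 and the genome build hg19 were used, and the notes give no role or order. The authors deposited FPKM, fragments scaled by transcript length and mapped total, with a confidence interval and a quantification status per row, per the file headers. The level of the interval and the normalization between columns are not given in the sources used here. Each knockdown table held 1 FPKM column for the control and 1 for the knockdown, so replicates were pooled by the authors. The name of the knockdown column does not say whether it holds siRNA 1 alone or both siRNAs, and the control column was identified as the one whose name lacks the target's number, in the only table the labels give to that set. By the interval widths described below, each column appears to hold 2 libraries, so a knockdown column does not appear to pool both replicates of both siRNAs. The deposited catalog listed exons of lncRNA transcripts with positions in hg19 and cross-references. The number of per-sample columns that were left unused was 0.

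The knockdown tables held 39925 rows under RefSeq identifiers. Symbols were found for 39101 (97.9%), 38599 in a RefSeq gene table and 502 through GENCODE release 29, and the remaining 824 rows, with 1.39% of the control FPKM in the lncRNA152 and 1.29% in the lncRNA67 table, were left out. FPKM was summed over the transcripts of a symbol, which gave 23043 genes, and interval half-widths were combined in quadrature. Genes with FPKM of at least 1 in either column and status OK in every row were kept, 11582 in the lncRNA152 and 11622 in the lncRNA67 table, which left out 80 and 77 expressed genes for their status. Log2 ratios were taken of FPKM + 1, which understates the difference of genes with low FPKM, and folds are on the same scale. Because each column was pooled, the limma test planned for replicate columns could not be made. The size rule planned for pooled columns was used, at least 1.5-fold in either direction, and its demand for the same direction with both siRNAs could not be applied to 1 knockdown column. "Intervals apart" means that the deposited intervals of the 2 columns did not overlap. The fragment totals of the knockdown libraries are unknown, and FPKM was not used as a count.

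The lncRNA67 knockdown column was found to have a break along the genome. Transcripts with at least 10 FPKM in the control, at least 5 FPKM in the knockdown and status OK in both were used. They were sorted by chromosome name as text and position, and the single division that best explained the ratio of relative interval widths was found. It explained 35.3% of the variance over 5903 transcripts in the lncRNA67 table, and 0.0856% over 6146 in the lncRNA152 table. Knockdown FPKM of the lncRNA67 set were therefore multiplied by 1.09 before and 2.21 after the break, so that the median log2 ratio of each part was 0, and both the deposited and the rescaled values are given. The lncRNA152 values were used as deposited.

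The 19 gene lists were fixed before the data were examined: DNA replication, mitosis and G2/M, G1/S regulators, CDK inhibitors, p53 targets, estrogen response, luminal epithelial markers, basal and mesenchymal markers, interferon response, unfolded protein and integrated stress response, cholesterol biosynthesis, hypoxia and glycolysis, apoptosis regulators, cytosolic ribosomal proteins, replication-dependent histones, immediate early and inflammatory genes, RNA interference machinery, markers of other cell types, and known lncRNAs. For each list the median log2 ratio was given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these columns with no p-value. Another 8 lists were written after the data were seen and appear among the other observations. The genes named in the text followed a rule fixed before the data were examined: the 12 highest and 12 lowest past the size rule in each knockdown, up to 4 members with the largest difference per list, the targets, and the 5 most abundant lncRNAs. The 12 highest and 12 lowest were all small RNAs with intervals that overlapped (0 of 12 apart in each direction), which poly(A)+ FPKM does not measure reliably, so the rule was applied again, after the data were seen, to genes other than small RNAs with intervals apart. Genes named for both knockdowns and CCNB1 in the lncRNA152 set were also chosen after the values were seen.

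Catalog loci were matched by position to the assembled loci of the unfractionated table (1480 of 1888). For each such locus the implied fragment number was taken from FPKM and its interval, assuming a half-width of 2 standard errors of a Poisson count, and it was whole within 0.02 for 87.9% of the 605 loci under 200 fragments. For these loci of the unfractionated library, the intervals and levels cover counting error only. The 95% interval of the median FPKM came from the binomial distribution of ranks.

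The steps were tested on simulated data drawn from the real genes' values and intervals, with 50 genes at each of 4 fold sizes. These changed genes were drawn only from genes with a mean of at least 5 FPKM over the 2 columns. The shares of them that passed therefore do not hold for genes with lower FPKM. In the simulation of the lncRNA152 comparison (11582 genes), 44 of 50 genes changed 2-fold and 49 of 50 changed 3-fold passed the size rule, 30 and 46 with intervals apart, and 991 of 11382 unchanged genes (8.71%) passed it, 56 with intervals apart. For the lncRNA67 comparison (11622 genes), 38 and 48 of 50 passed, 22 and 37 with intervals apart, and 1900 of 11422 unchanged genes (16.6%) passed, 55 with intervals apart. Alternatives were pseudocounts of 0.1 and 5, no FPKM minimum and one of 5, a 2-fold threshold, all statuses, intervals apart, rescaling to a median of 0, and, added after the data were seen, rescaling per part, each part alone and leaving out small RNAs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.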

Results

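Long noncoding RNAs (lncRNAs), transcripts without an apparent coding sequence, were examined in MCF-7, an estrogen receptor-positive human breast cancer cell line. The series held 25 poly(A)+ RNA libraries in 13 groups. Of these, 12 belonged to knockdown experiments, in which cells received a control siRNA or 1 of 2 siRNAs against an RNA named lncRNA152 or lncRNA67, with 2 libraries per group. A further 12 libraries came from cytoplasmic, nuclear and chromatin fractions with and without 100 nM estradiol and were not analysed here, and 1 library came from unfractionated RNA. The deposited values were a catalog of lncRNAs with positions, FPKM for the unfractionated library, and 1 table per knockdown with 1 pooled FPKM and its confidence interval for the control and for the knockdown. Fragment totals of the knockdown libraries were not given, but the intervals showed the precision. Over 6146 transcripts of at least 10 FPKM in the lncRNA152 control and 5 FPKM in its knockdown column, the median half-width was 26.8% of the FPKM in the control column and 25.1% in the knockdown column. No difference between a knockdown and its control had a replicate check, since each column pooled its libraries, and so no p-value was computed.

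The catalog named 1888 lncRNA loci with 2305 transcripts on 23 chromosomes, 945 on the plus and 943 on the minus strand. LncRNA genes in it were simple: 1619 loci had 1 transcript and 988 transcripts (42.9%) had a single exon. Single-exon lncRNAs had a median length of 2205 bp (quartiles 1348 and 3597 bp), against 943 bp (quartiles 405 and 2081 bp) for spliced lncRNAs. Cross-references linked 1239 loci to LNCipedia, 802 to GENCODE, 576 to RefSeq and 285 to a human lincRNA catalog, and 612 loci (32.4%) had none. LncRNA152 lay on chromosome 15 from 69853776 to 69863843 on the plus strand (hg19), with 2 transcripts of 5 exons each, 2082 and 1845 bp long, and its RefSeq cross-reference was DRAIC, a known breast and prostate lncRNA. LncRNA67 was a single-exon transcript of 5362 bp on the minus strand of chromosome 3, from 33835137 to 33840498, and overlapped the start of PDCD6IP, the gene of the endosomal sorting protein ALIX.

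In unfractionated RNA the catalogued lncRNAs had a lower median level than protein-coding genes and a narrower spread. The 1480 lncRNA loci matched by position had a median of 1.94 FPKM (95% interval of the median 1.83 to 2.07, binomial over loci, quartiles 1.02 and 4.26), and the 18403 protein-coding genes had a median of 3.16 FPKM (quartiles 0.0297 and 15.5). At 10 FPKM or more there were 161 lncRNA loci (10.9%) and 6095 protein-coding genes (33.1%), whereas at 1 FPKM or more there were 1119 lncRNA loci (75.6%) and 10764 protein-coding genes (58.5%). The lncRNAs were matched assembled loci, of which only 4 were at 0, while the protein-coding genes were all those annotated, and the 15424 of them above 0 had a median of 5.97 FPKM with 69.8% at 1 FPKM or more. Spliced lncRNAs had a median of 2.61 FPKM and single-exon lncRNAs 1.41 FPKM. LncRNA152 was at 8.93 FPKM (deposited interval 8.45 to 9.40), at percentile 87.9 of the lncRNA loci, and LncRNA67 was at 3.13 FPKM (2.99 to 3.26), at percentile 66.8.

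The 5 most abundant lncRNAs held 24.5% of the summed lncRNA FPKM. LncRNA2 (1442 FPKM, chromosome 1, 567064 to 568365) and LncRNA3 (785 FPKM, chromosome 1, 569019 to 570304) lie in a copy of mitochondrial DNA in the nuclear genome, so their values are uncertain, because reads from mitochondrial transcripts can align there. LncRNA561 (344 FPKM, chromosome 17, 16342364 to 16344841) corresponded to SNHG29 and LncRNA847 (268 FPKM, chromosome 20, 47895121 to 47905799) to ZFAS1, both hosts of small nucleolar RNAs, and LncRNA618 (287 FPKM, chromosome 17, 60318922 to 60324443) had no RefSeq cross-reference. LncRNA618 was 211 bp long with 1370 implied fragments, against up to 827 bp and 14760 fragments for LncRNA561, so its rank depends on the scaling by length. By the fragments that FPKM and intervals imply, catalogued lncRNAs held 2.05% of the table's fragments. This share is uncertain, because the implied numbers were checked only for catalog loci under 200 fragments and not for the mRNA rows. It also includes LncRNA2 and LncRNA3. A single library was measured, so these levels have no replicate error.

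**Figure D1:**
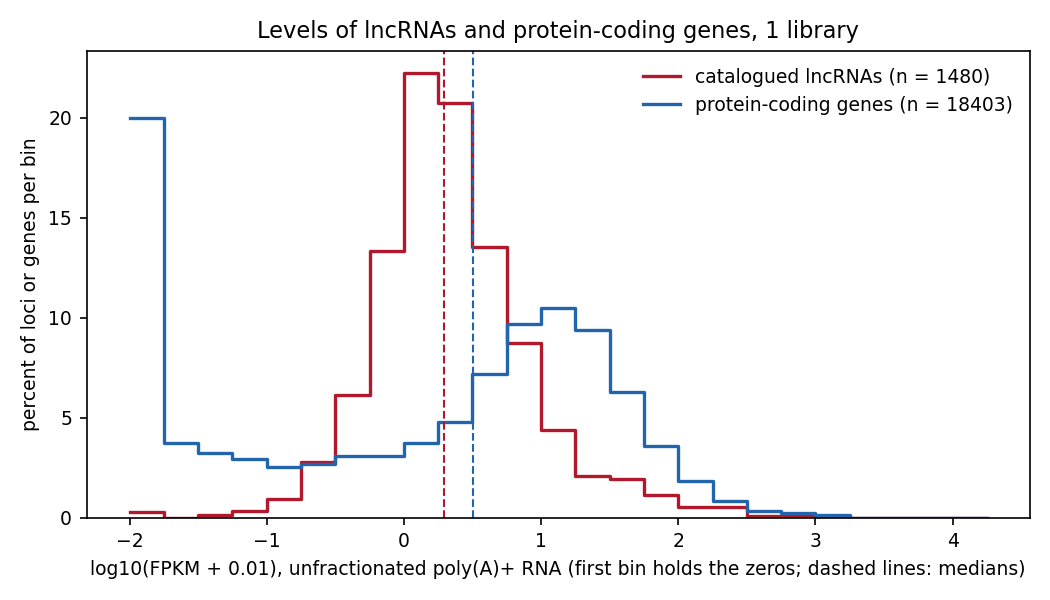
Distribution of log10(FPKM + 0.01) in the single unfractionated library for 1480 catalogued lncRNA loci and 18403 protein-coding genes, as percent of loci or genes per bin, with genes at 0 in the first bin. Dashed lines mark the medians of 1.94 FPKM for lncRNAs and 3.16 FPKM for protein-coding genes, and the lncRNAs form a single peak around their median.

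The knockdowns asked which genes depend on each lncRNA. The targeted RNA was measured first. DRAIC, the RefSeq gene of LncRNA152, was at 27.8 FPKM (deposited interval 20.6 to 34.9) with control siRNA and at 6.11 FPKM (4.01 to 8.22) in the lncRNA152 knockdown column, 24.7% of the control on the scale of FPKM + 1, with the intervals apart. In the lncRNA67 set DRAIC was at 24.1 FPKM in the control, and in the knockdown at 23.1 FPKM as deposited and 25.2 FPKM after the rescaling described below, which reversed this small difference. LncRNA67 itself was not a feature of the RefSeq-based knockdown tables, so its own level was not measured here. PDCD6IP beside it was at 27.5 FPKM in the lncRNA67 control (19.1 to 35.9) and in the knockdown at 14.6 FPKM, lower, as deposited and at 32.3 FPKM (14.3 to 50.2), higher, after rescaling, with overlapping intervals.

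With lncRNA152 knocked down, the genes of cell division were lower almost without exception among those listed. All 52 members of the mitosis and G2/M list were lower by at least 1.5-fold, 50 of them with intervals apart, and their median log2 ratio was −1.88. UBE2C, which tags mitotic cyclins for destruction, was at 150 FPKM in the control (110 to 189) and 30.2 FPKM in the knockdown, with intervals apart. ANLN, a scaffold of the cleavage furrow, was at 67.8 and 13.3 FPKM. FOXM1, a transcription factor of mitotic genes, was at 76.7 and 15.4 FPKM, and SPC24, a kinetochore protein, at 20.6 and 3.71 FPKM. CCNB1, the cyclin of mitotic entry, was at 65.8 FPKM in the control and 16.1 FPKM in the knockdown.

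All 46 measured DNA replication genes were lower as well, 39 of them with intervals apart, with a median log2 ratio of −1.38. Thymidine kinase TK1 was at 75.3 FPKM in the control and 16.6 FPKM in the knockdown, and the replication initiation factor CDC45 at 8.36 and 1.37 FPKM. The helicase subunit GINS2 was at 59.3 and 14.8 FPKM, and the initiation factor MCM10 at 6.18 and 0.932 FPKM. Of 24 G1/S regulators, 14 were lower and 2 higher (median log2 −0.72). MYBL2, a transcription factor of cycling cells, was at 116 and 22.9 FPKM, and E2F1 at 26.1 and 5.93 FPKM. The phosphatase CDC25A was at 8.16 and 1.80 FPKM, and cyclin CCNE2 at 10.5 and 2.54 FPKM. The medians of these 3 lists lay below those of all 10000 random lists of matched expression.

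Cyclin-dependent kinase inhibitors were mixed. CDKN1A, the p21 inhibitor, was at 46.9 FPKM in the control and 91.5 FPKM in the lncRNA152 knockdown with overlapping intervals, while CDKN1B was at 33.1 and 18.9 FPKM. Of 5 measured inhibitors, 1 was higher and 2 were lower (median log2 −0.42, percentile 2.88). Of 26 p53 targets, 5 were higher and 5 lower (median 0.11, percentile 97.3), among them BBC3 at 1.77 and 3.95 FPKM, TNFRSF10B at a log2 ratio of −1.01 and DDB2 at 17.9 and 9.98 FPKM. Of 24 apoptosis regulators, 1 was higher and 1 lower (median 0.12), the lower one being the mitotic survivin gene BIRC5 at 46.9 and 9.85 FPKM.

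Among the genes of hormone response and cell identity, 6 of 24 estrogen response genes were lower and 1 higher with lncRNA152 knockdown (median log2 −0.21, percentile 2.11). The estrogen-induced secreted peptide TFF1 was at 54.1 FPKM in the control and 18.9 FPKM in the knockdown, and MYBL1 at 1.92 and 0.331 FPKM. MYB was at 16.2 and 8.07 FPKM and the growth factor AREG at 1.43 and 0.387 FPKM. Luminal epithelial markers had a median log2 ratio of 0.24 (percentile 99.8), with 3 higher and 1 lower of 18. E-cadherin, CDH1, was at 128 FPKM in the control (98.2 to 157) and 355 FPKM in the knockdown (261 to 448). The mucin MUC1 was at 24.4 and 63.7 FPKM and MLPH at 46.3 and 92.0 FPKM, whereas the estrogen receptor ESR1 was at 157 and 96.4 FPKM with overlapping intervals. Of 8 basal and mesenchymal markers, 1 was lower, CD44 at 4.67 and 2.66 FPKM.

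Of 24 cholesterol biosynthesis genes, 9 were lower and 0 higher (median log2 −0.35, percentile 0.07), including ACAT2 at 43.1 and 16.8 FPKM, EBP at 94.4 and 48.8 FPKM and MVD at 32.7 and 16.8 FPKM. Of 28 genes of the unfolded protein and integrated stress response, 6 were lower and 1 higher (median −0.10), with the serine synthesis enzyme PHGDH at 61.3 and 35.1 FPKM. Hypoxia and glycolysis genes (1 higher and 1 lower of 21, median −0.03), the RNA interference machinery (0 and 0 of 13, median −0.25) and interferon response genes (0 higher and 1 lower of 17, median −0.01) had few members past 1.5-fold, and of the markers of other cell types only 1 was measured. Of 12 immediate early and inflammatory genes, 2 were higher and 2 lower (median 0.02). Of 14 replication-dependent histones, 2 were higher and 5 lower (median 0.08), though these transcripts largely lack poly(A) tails and are poorly captured by poly(A)+ libraries.

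Of the 50 cytosolic ribosomal protein genes 0 passed 1.5-fold, although their median log2 ratio of 0.17 was high among random lists (percentile 99.9). RPL3 was at 924 FPKM in the control and 1316 FPKM in the knockdown, and RPLP1 at 1466 and 2035 FPKM. Known lncRNAs had a median log2 ratio of 0.37, above all 10000 random lists, with 6 higher and 2 lower of 18. The paraspeckle RNA NEAT1 was at 11.5 FPKM in the control (8.30 to 14.7) and 39.7 FPKM in the knockdown (31.0 to 48.5), and the nuclear speckle RNA MALAT1 at 171 and 328 FPKM.

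Over all 11582 genes expressed in the lncRNA152 table, 627 were higher and 1061 lower by at least 1.5-fold, 239 and 560 of them with intervals apart, and the median log2 ratio was −0.03. In the simulation, interval error alone took 991 of the 11382 unchanged genes past 1.5-fold, 56 of them with intervals apart, so single genes within overlapping intervals are uncertain. The same simulation overstated the error in the lncRNA67 set, as given below. It therefore does not tell how many of the counted genes are error here either. The genes with the highest ratios among those with intervals apart, small RNAs left out, included the lipid oxidase CYP4B1 (9.51 and 36.1 FPKM), BCAS1 (9.94 and 35.7 FPKM) and ENPP5 (3.54 and 14.0 FPKM). They also included the glycogen regulator PPP1R3C (7.58 and 26.8 FPKM), TBC1D5 (2.24 and 9.88 FPKM) and TSPAN31 (7.49 and 31.7 FPKM). The lowest included CEP55 (38.3 and 5.80 FPKM), the mitotic kinase PBK (22.3 and 3.84 FPKM), the DNA methylation factor UHRF1 (16.8 and 2.76 FPKM), CENPM (46.6 and 9.16 FPKM) and CDKN3 (66.9 and 13.9 FPKM), along with MYBL2, UBE2C, ANLN, FOXM1 and SPC24. SMN1 (0.558 and 22.3 FPKM), CRYM (listed at 0 and 3.11 FPKM), SERF1A (0.00383 and 3.01 FPKM), TMEM256-PLSCR3 (0.00818 and 6.48 FPKM), PEDS1-UBE2V1 (17.5 FPKM and listed at 0), RCHY1 (0.00226 and 4.91 FPKM) and CNKSR1 (4.82 and 0.00115 FPKM) also stood at the extremes. SMN1 and SERF1A have near-identical copies, and TMEM256-PLSCR3 and PEDS1-UBE2V1 are readthrough transcripts that overlap other genes. All 7 were at or below 0.558 FPKM in 1 column and at 3.01 FPKM or more in the other, so these values are uncertain, and the cause was not tested.

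**Figure D2:**
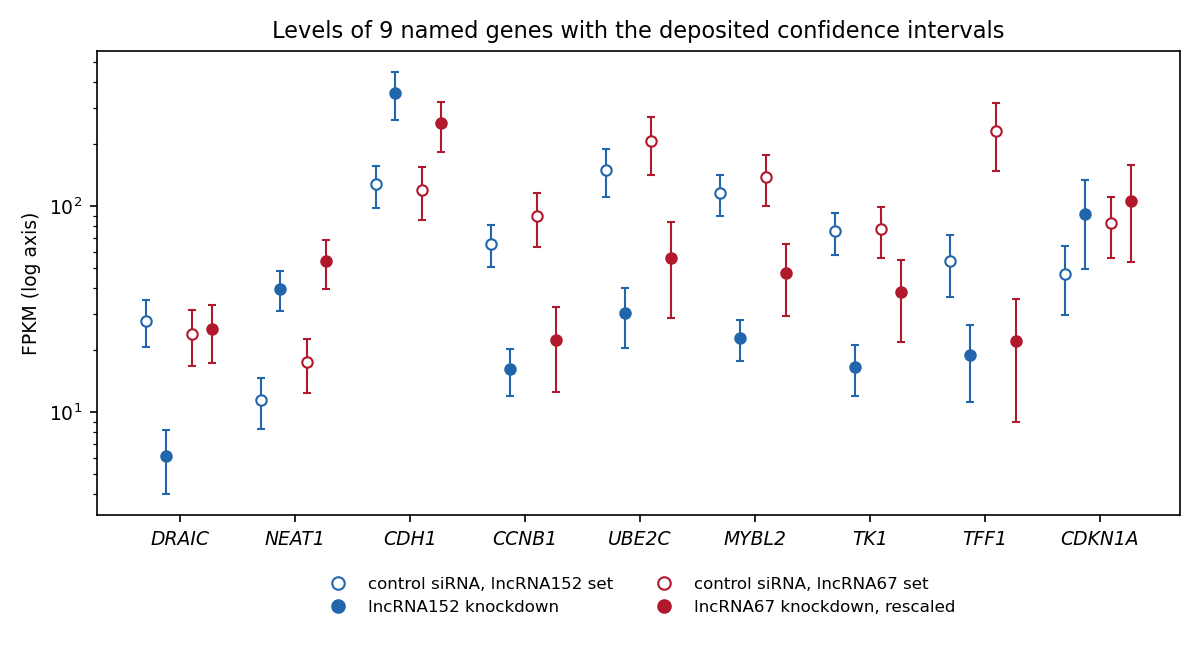
FPKM on a log axis for 9 named genes in the control siRNA columns (open) and knockdown columns (filled) of the lncRNA152 and lncRNA67 sets, with the deposited confidence intervals as bars and the lncRNA67 knockdown rescaled per part of the genome. DRAIC is at 27.8 and 6.11 FPKM in the lncRNA152 set and at 24.1 and 25.2 FPKM in the lncRNA67 set (23.1 as deposited, the reverse direction), as CDKN1A goes from 83.2 to 106 rescaled but to 48.1 as deposited, while CCNB1, UBE2C, MYBL2, TK1 and TFF1 are lower in both knockdowns.

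In the lncRNA67 set, mitotic genes were again lower in the knockdown than in its control, but the size of the difference depended on the part of the genome. The deposited knockdown column was not uniform along the chromosomes. With chromosomes ordered by name as text, the knockdown values had a median log2 ratio to the control of −0.19 over 2536 transcripts up to position 85840607 on chromosome 16, and of −1.14 over 3367 transcripts from position 87425801 onwards. The relative interval width was 1.02 times that of the control before this break and 1.43 times after it, and no such break was found in the lncRNA152 table. The interval widths of transcripts with a single fragment showed 2 libraries in each column, and those of 1 library of the lncRNA67 knockdown ended at the break, with 60 transcripts before it and 0 after it. By these widths, the knockdown values after the break appear to rest on 1 library. With 2 libraries per column, a knockdown column also does not appear to pool both replicates of both siRNAs. Values are given as deposited and after rescaling by 1.09 before and 2.21 after the break, which sets the median log2 ratio of each part to 0.

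**Figure D3:**
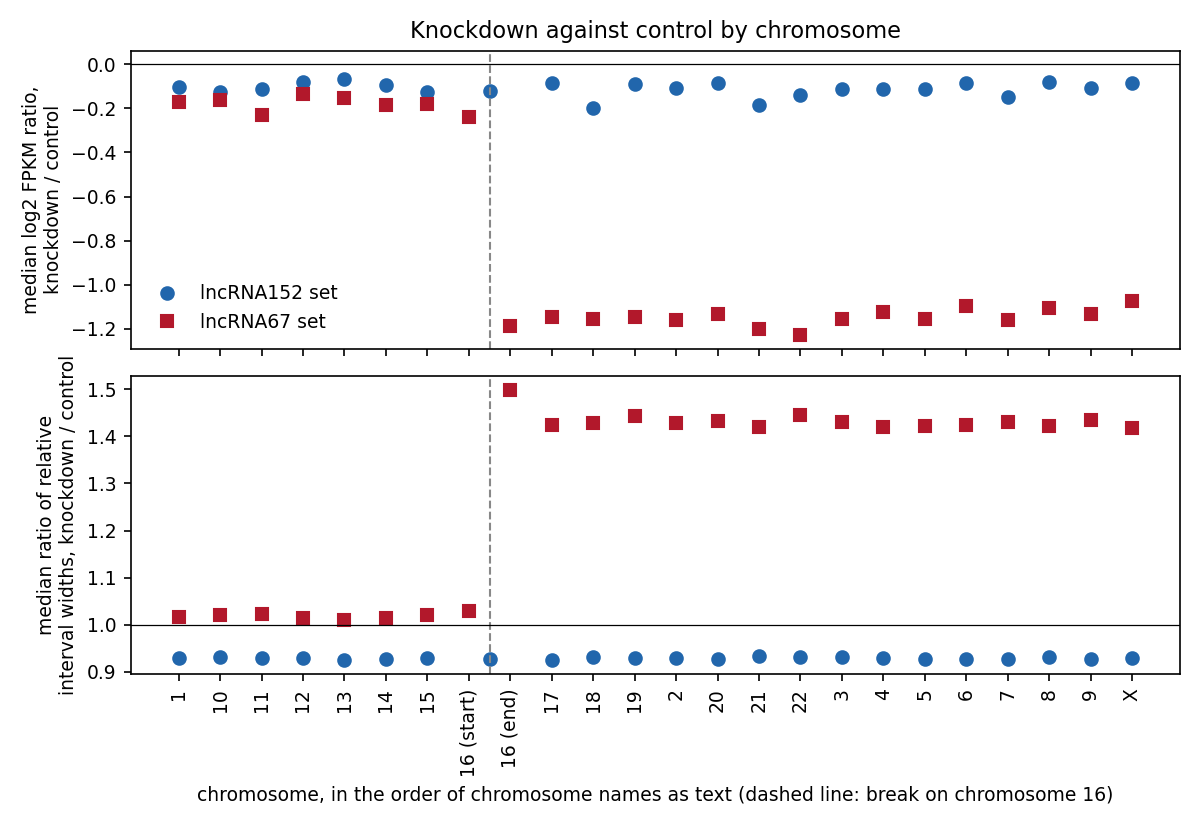
Median log2 FPKM ratio of knockdown to control (top) and median ratio of relative interval widths (bottom) per chromosome, in the order of chromosome names as text, for both knockdown sets. In the lncRNA67 set the ratio goes from −0.24 at the start of chromosome 16 to −1.19 at its end and stays below −1.0 on every chromosome after it, and the lncRNA152 set stays between −0.20 and −0.07.

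Of the 52 mitosis and G2/M genes, 47 were lower by at least 1.5-fold with lncRNA67 knockdown after rescaling, 30 of them with intervals apart, and the median log2 ratio was −1.32 (−2.02 as deposited). CCNB1 was at 89.8 FPKM in the control and 10.1 FPKM in the knockdown as deposited (22.4 FPKM rescaled), and ANLN at 60.6 and 6.85 FPKM (15.1 rescaled). The motor protein KIF20A was at 35.2 and 3.97 FPKM (8.77 rescaled) and the kinase AURKB at 34.5 and 3.93 FPKM (8.68 rescaled). These 4 genes all lie after the break. Before it, where both libraries count, the rescaled median of the 22 mitotic genes was −0.84, with 17 lower by at least 1.5-fold, and after it the median of the other 30 was −1.64, with all 30 lower.

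DNA replication genes were lower mostly after the break. Rescaled, 25 of 46 were lower and 0 higher with lncRNA67 knockdown (median log2 −0.62, −1.53 as deposited), but only 3 of 19 before the break (median −0.34) and 22 of 27 after it (median −0.79). DSCC1 was at 11.0 FPKM in the control and 1.70 FPKM as deposited (3.75 rescaled), the licensing factor CDT1 at 19.4 and 3.44 FPKM (7.59 rescaled), and TK1 at 77.4 and 17.4 FPKM (38.4 rescaled). Of 23 G1/S regulators, 7 were lower and 0 higher (median −0.30, −0.95 as deposited), all 7 after the break, with CCNE2 at 13.2 and 1.43 FPKM (3.15 rescaled) and MYBL2 at 138 and 21.5 FPKM (47.5 rescaled). The rescaled medians of the mitosis and replication lists lay below those of all 10000 random lists, and the G1/S median was at percentile 0.015.

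TFF1 had the lowest ratio of the estrogen response genes with lncRNA67 knockdown, at 232 FPKM in the control (148 to 315) and 10.0 FPKM as deposited, or 22.2 FPKM rescaled, with intervals apart. In the lncRNA152 control TFF1 was at 54.1 FPKM (36.2 to 72.0), so it also differed between the 2 control siRNA columns with intervals apart. Its difference from either knockdown may therefore include variation between cultures, which was not tested. Of 24 members, 5 were lower and 1 higher after rescaling (median log2 −0.17, percentile 2.36), with a median of 0.14 over the members before the break and of −0.35 over those after it. MYBL1 was at 3.70 and 0.511 FPKM (1.13 rescaled), and the chemokine CXCL12 at 12.2 and 22.3 FPKM (24.3 rescaled). CDH1 was at 120 FPKM in the control and 231 FPKM as deposited (252 rescaled, intervals apart) and MUC1 at 21.6 and 44.9 FPKM (49.0 rescaled). The 18 luminal markers had a median of 0.09 rescaled (2 higher and 0 lower, percentile 77.7) and, in the reverse direction, −0.95 as deposited (2 higher and 12 lower). Of 7 basal and mesenchymal markers, 2 were higher, CAV1 at 3.02 and 3.13 FPKM (6.92 rescaled) and CAV2 at 0.949 and 1.66 FPKM (3.66 rescaled), with a median of 0.22 rescaled and, reversed, −0.16 as deposited.

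Cholesterol biosynthesis genes had a rescaled median log2 ratio of −0.50 (−1.31 as deposited), below all 10000 random lists, with 8 lower and 0 higher of 25. MVD was at 33.7 and 6.38 FPKM (14.1 rescaled), EBP at 94.8 and 19.6 FPKM (43.3 rescaled) and PCSK9, which lies before the break, at 1.61 and 0.322 FPKM (0.351 rescaled). Of 27 stress response genes, 4 were lower and 1 higher (median −0.13, percentile 4.37, −0.99 as deposited), the higher one being DDIT4, an inhibitor of growth signalling, at 25.6 and 60.2 FPKM (65.6 rescaled). Of 27 p53 targets, 5 were higher and 2 lower after rescaling (median 0.17, percentile 99.0), but 1 higher and 12 lower as deposited (median reversed to −0.37). BTG2 was at 24.0 and 48.8 FPKM (53.2 rescaled) and GDF15 at 38.9 and 5.60 FPKM (12.4 rescaled). Of 5 cyclin-dependent kinase inhibitors 1 was higher, CDKN2B at 3.13 and 4.06 FPKM (8.98 rescaled), and their median was 0.35 rescaled but reversed to −0.42 as deposited. Apoptosis regulators had a median of 0.25 (percentile 99.9, reversed to −0.45 as deposited), with 3 higher and 2 lower of 23 rescaled, the lower ones being BIRC5 and BAX. As deposited, 1 was higher and 10 were lower.

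Ribosomal protein genes had a rescaled median log2 ratio of 0.39 (percentile 100) with lncRNA67 knockdown and 7 of 50 higher, against the reverse direction, a median of −0.65 with 30 lower and 0 higher, as deposited. The reversal came from the 38 members after the break (−0.71 as deposited, 0.43 rescaled), whereas the 12 before it had medians of 0.18 as deposited and 0.30 rescaled. RPL3 was at 821 FPKM in the control and at 577 FPKM, lower, as deposited but 1276 FPKM, higher, rescaled, and RPL18A likewise at 187, 132 and 293 FPKM. Known lncRNAs likewise had a rescaled median of 0.47 (percentile 100, reversed to −0.28 as deposited), with 8 higher and 0 lower of 18 rescaled, against 3 higher and 7 lower as deposited. NEAT1, before the break, was at 17.5 FPKM in the control and 49.6 FPKM as deposited (54.1 rescaled), and HOTAIR at 7.51 and 16.3 FPKM (17.8 rescaled). ZFAS1 was at 143 FPKM in the control and at 133 FPKM, lower, as deposited but 295 FPKM, higher, rescaled. After rescaling, interferon response genes (1 higher and 1 lower of 18, median 0.11), hypoxia and glycolysis genes (2 and 1 of 21, median 0.01) and histones (3 and 2 of 12, median 0.12) had members past 1.5-fold in both directions, and their medians were reversed as deposited (−0.52, −0.30 and −0.82). Immediate early and inflammatory genes also went both ways (2 and 2 of 11, median −0.10, −0.70 as deposited), and of the RNA interference machinery 0 of 13 passed (median −0.15, −0.58 as deposited).

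Over all 11622 genes expressed in the lncRNA67 table, 194 were higher and 6106 lower by at least 1.5-fold as deposited, with a median log2 ratio of −0.64, and 5789 of the lower genes lay after the break. Rescaled per part, 792 were higher and 756 lower, 78 and 170 of them with intervals apart. Interval error alone took 1900 of 11422 simulated unchanged genes past 1.5-fold, and 55 with intervals apart. The 1900 are more than the 2 rescaled counts together, so the simulation overstates the error. It therefore does not tell how many of the counted genes are error. The genes named next are those with intervals apart. The highest after rescaling were the selenium carrier SELENOP (28.0 FPKM in the control, 46.9 as deposited, 104 rescaled), the protease ADAMTS9 (1.41, 3.49 and 7.72 FPKM), the kinase MAPK11 (2.52, 5.22 and 11.5 FPKM), ENPP5 (4.29, 7.92 and 17.5 FPKM) and CLEC7A (3.99, 14.9 and 16.2 FPKM). They were followed by VMO1 (15.3, 24.7 and 54.6 FPKM), ITGB6 (0.767, 2.23 and 4.92 FPKM), STRA6 (1.25, 5.96 and 6.50 FPKM), RNF144B (4.20, 7.04 and 15.6 FPKM) and DHRS2 (1.18, 5.39 and 5.88 FPKM). The lowest were TFF1, PCBD1 (67.1, 13.6 and 14.9 FPKM), the spindle proteins SPAG5 (25.9, 2.60 and 5.74 FPKM), TPX2 (69.3, 8.29 and 18.3 FPKM) and FAM83D (30.7, 3.49 and 7.72 FPKM), and CCNB1, ANLN, KIF20A and AURKB. PLSCR3 (0.00932, 8.95 and 19.8 FPKM), NEK3 (0.00264, 2.13 and 2.32 FPKM), TMEM256-PLSCR3 (17.6, 0.00282 and 0.00623 FPKM), SMN1 (9.05, 0.0209 and 0.0463 FPKM) and RPL21 (12.1, 0.00342 and 0.00373 FPKM) likewise were near 0 in 1 column and are uncertain, with the cause not tested.

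**Figure D4:**
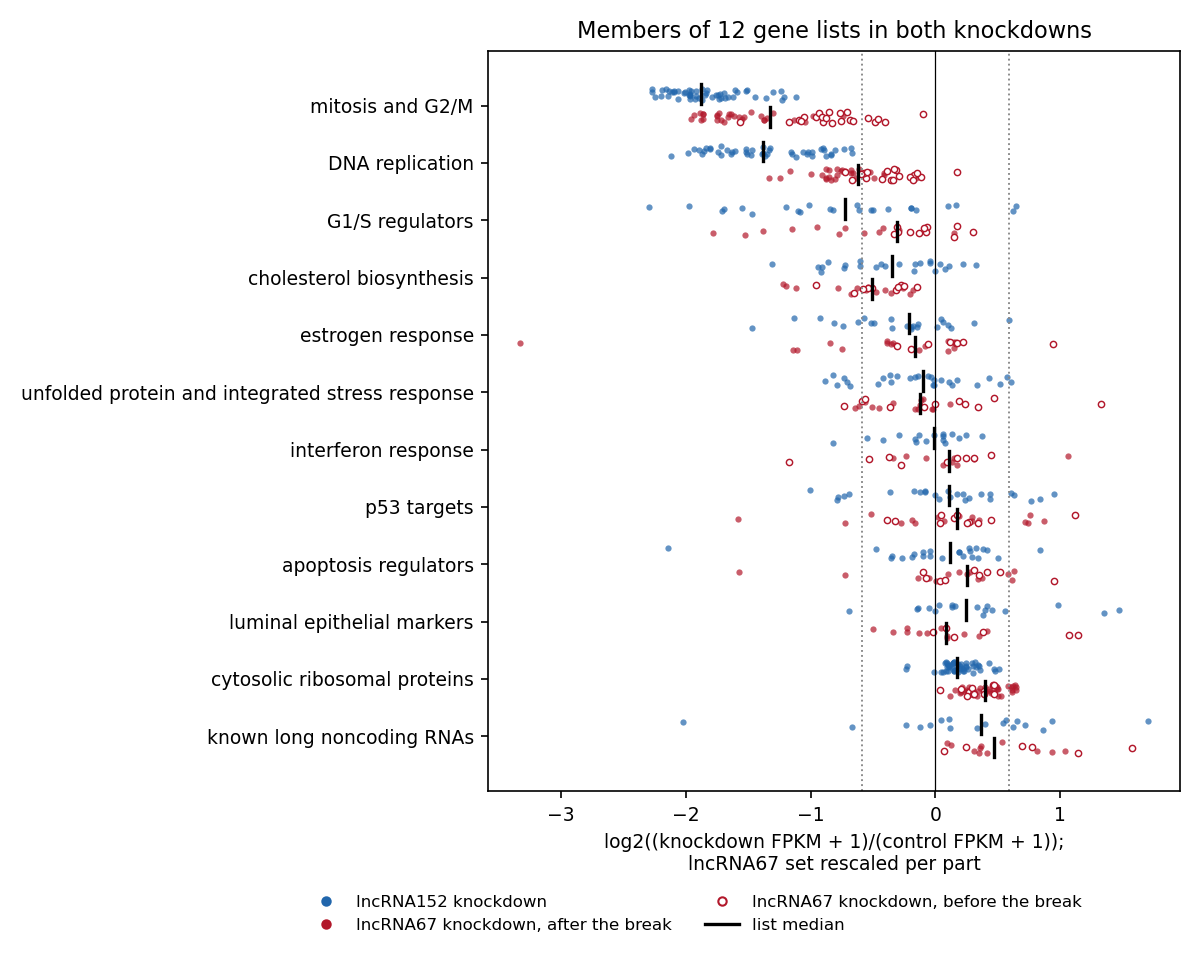
Log2((knockdown FPKM + 1)/(control FPKM + 1)) of the members of 12 gene lists in the lncRNA152 knockdown (blue) and the lncRNA67 knockdown rescaled per part (red, filled after and open before the break on chromosome 16), with list medians as black bars and dotted lines at 1.5-fold. Mitotic genes have medians of −1.88 and −1.32, DNA replication genes −1.38 and −0.62 and ribosomal proteins 0.17 and 0.39 (the latter reversed to −0.65 as deposited), and the open mitotic points lie closer to 0 than the filled ones.

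The same genes tended to differ in the same direction in both knockdowns, each measured against its own control siRNA. Across 11205 genes without small RNAs, the log2 ratios had a Pearson r of 0.63 and a Spearman rho of 0.62, and across all 11288 genes r was 0.50 and rho 0.61, with genes not being independent replicates. Among all genes, 298 were higher in both with the lncRNA67 column rescaled, against 38.4 for independent lists, and 392 were lower in both, against 64.1. With intervals apart in both sets, 35 were higher and 106 lower. As deposited, 79 were higher and 734 lower in both, against 8.10 and 539 for independent lists (r = 0.39).

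ENPP5 (log2 ratios 1.72 with lncRNA152 and 1.81 with lncRNA67 knockdown), NEAT1 (1.70 and 1.58), PIK3IP1, an inhibitor of PI3K signalling (1.45 and 1.61), the stress sensor ATF6B (1.28 and 1.24), SELENOP (1.18 and 1.85), CDH1 (1.47 and 1.07) and S100A14 (1.03 and 1.22) were higher in both. UBE2C (−2.27 and −1.86), CCNB1 (−1.96 and −1.96), ANLN (−2.27 and −1.93), TOP2A, the topoisomerase of dividing cells (−2.11 and −1.74), the importin KPNA2 (−1.76 and −1.83) and TRIP13 (−2.09 and −1.77) were lower in both, and all of these lower genes lie after the break. Restricted to the 4321 genes before the break, 93 were higher and 87 lower in both (12.7 and 17.0 for independent lists), with r = 0.45. Opposite directions were seen for 32 genes, or 14 with small RNAs left out. Intervals were apart in both sets for 2 of them, SMN1 and TMEM256-PLSCR3, whose values are uncertain.

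**Figure D5:**
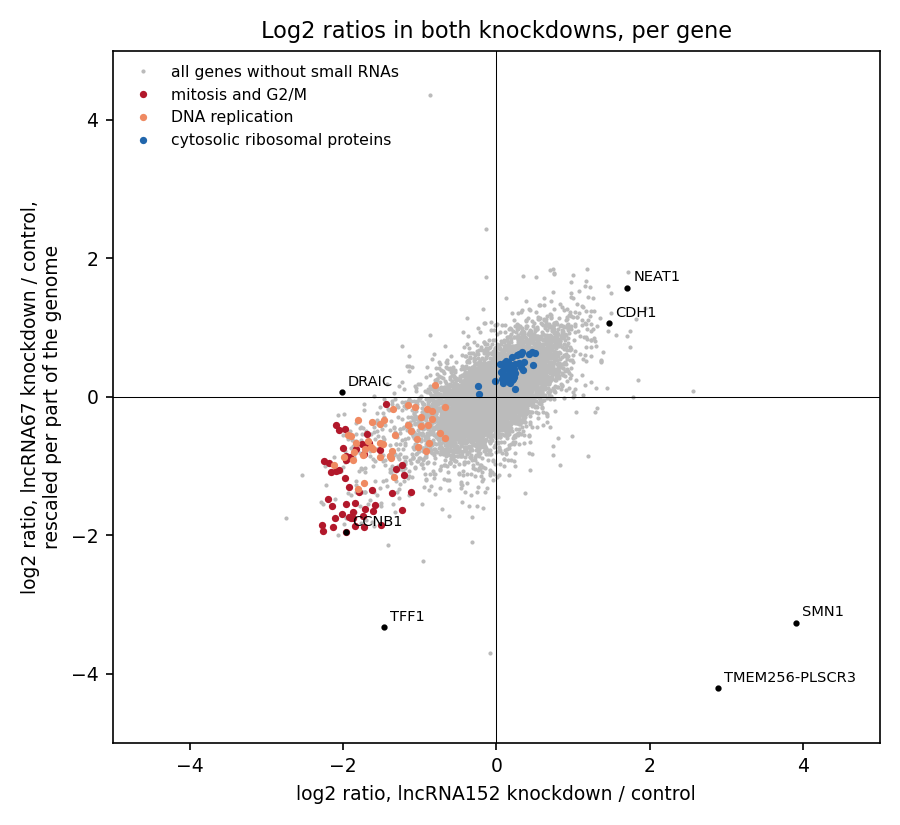
Log2 ratio of knockdown to control per gene in the lncRNA152 set (horizontal) and in the lncRNA67 set rescaled per part of the genome (vertical), for 11205 genes without small RNAs, with 3 gene lists coloured and 7 genes named. Mitosis and DNA replication genes lie in the lower left, ribosomal protein genes mostly just above 0 on both axes (median −0.65, the reverse direction, in the lncRNA67 set as deposited), and DRAIC is low only on the horizontal axis.

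LncRNAs annotated in RefSeq were higher more often than lower in both tables. Of 285 expressed lncRNA genes, 35 were higher and 8 lower with lncRNA152 knockdown (median log2 0.16), while protein-coding genes had 532 higher and 986 lower of 10917 (median −0.04). With lncRNA67 knockdown and rescaling, 48 were higher and 7 lower of 289 (median 0.23, reversed to −0.34 as deposited, against −0.65 for protein-coding genes). Of the catalogued lncRNAs, 178 were measured through their RefSeq cross-reference. With lncRNA152 knockdown 23 of these were higher, NEAT1, MALAT1, SNHG33 (3.39 and 8.89 FPKM), LITATS1 (2.07 and 5.84 FPKM), ATP2B1-AS1 (2.29 and 6.03 FPKM) and WDFY3-AS2 (2.14 and 5.40 FPKM) with intervals apart, and 5 were lower, DRAIC with intervals apart. With lncRNA67 knockdown 32 were higher after rescaling and 2 lower, NEAT1 with intervals apart.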

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

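The tests of random chromosome orders, of the difference between the 2 parts, of the interferon list and of the parts of the mitotic list were chosen after the results were seen. The other tests were written before their own results, but for patterns already seen in these data.

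The deposited lncRNA67 knockdown values were lower than the control on most chromosomes. A lower level of all RNAs, or a few genes taking more of the library, would act alike on every chromosome, but the median log2 ratio after the break minus that before it was −0.96. Random orders of the chromosomes, with the measured values kept, gave at most 26.1% of the variance at the best division over 1000 orders, below the 35.3% of the text order. This concerns the order of the chromosomes and does not measure chance differences between them. Of the single-fragment transcripts with the less common interval width, 0% lay after the break (0 of 60, against 75.9% of the 435 with the common width), so a candidate explanation is a library whose alignments ended at that point of a file sorted by chromosome name as text. No biological explanation was tested, because the break follows a text order and not the genome.

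Mitotic genes were lower in both knockdowns, and more so in the lncRNA67 set after the break. The incomplete library is not the whole cause, since the median before the break was −0.84, below the central 95% of random lists of genes there (−0.15 to 0.10), and GC content and transcript length are argued against by medians that lay −1.80 (lncRNA152) and −1.30 (lncRNA67) from those of lists matched on both. Interferon response genes had list medians of −0.0148 (lncRNA152) and 0.11 (lncRNA67, reversed to −0.52 as deposited), which argues against a response larger than that to the control siRNA. A response to transfected RNA shared with the control siRNA would cancel in the ratio, so these medians cannot test it. The median differed between the parts by −0.80 in the lncRNA67 set and 0.10 in the lncRNA152 set for the same genes, a difference of −0.91. Mitotic genes may thus have responded less in the library that ended at the break. If genes in both parts respond alike (49.3% weight for the other library), the medians imply 0.790-fold for mitosis and 0.998-fold for DNA replication in it, and 1.12-fold for ribosomal proteins. These are nearer 1 than after the break (0.320 for mitosis and 1.35 for ribosomal proteins). For G1/S regulators the medians imply 1.27-fold, the opposite direction (0.595 after), and for known lncRNAs 2.00-fold (1.31 after). In the lncRNA152 set the parts of these 2 lists had log2 medians of −0.63 and −0.97, and of 0.59 and 0.23. Their differences lie within the spread of the medians (SDs over resampled members 0.24 and 0.36, 0.52 and 0.16). For known lncRNAs the lncRNA67 parts had log2 medians of 0.73 and 0.39 (SDs 0.29 and 0.11), a similar gap. Members of the 2 parts may thus differ, so these 2 implied folds cannot decide whether all genes responded less in that library. The siRNA or replicate behind either library is not given, and a dependence of mitotic genes on both lncRNAs, or on slower growth after either siRNA, stays open and untested. The agreement of 2 siRNAs per target could not be checked, so effects of an siRNA apart from its target are not separated from these.

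SMN1 (log2 ratio 3.90 with lncRNA152 and −3.26 with lncRNA67 knockdown) and TMEM256-PLSCR3 (2.89 and −4.21) stood out because the 2 knockdowns differed in direction with intervals apart in each. At the locus of TMEM256-PLSCR3, PLSCR3 went the other way in the lncRNA67 set. PLSCR3 was at 0.00932 FPKM in the control and 19.8 FPKM rescaled, and TMEM256-PLSCR3 at 17.6 and 0.00623 FPKM. A lower level of the locus as a whole is therefore not shown. The differences between the 2 knockdowns were not tested.

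In the unfractionated library, 406 of the 435 assembled loci outside the catalog stood above 3 fragments. The median over all 435 was 0.962 FPKM, and no comparison used these data.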

How the results depend on the processing

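Rescaling per part, each part alone and leaving out small RNAs were chosen after the data were seen. No paired analysis was possible because each condition was deposited as 1 pooled column. Each siRNA alone, the agreement of 2 siRNAs, leaving out a replicate, a replicate block, limma and the fraction and estradiol results were not run for the same reason or for want of columns. The directions of the mitosis and DNA replication medians were the same under every alternative run, and the depth of the knockdown libraries is unknown.

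With lncRNA152 knockdown, 942 genes were higher at a pseudocount of 0.1 and 288 higher and 584 lower at a pseudocount of 5, 142 and 416 at a 2-fold threshold, and 239 and 560 with intervals apart, each smaller or larger by construction. For lncRNA67 as deposited, 90 were higher at a pseudocount of 5, 69 higher and 3319 lower at 2-fold, 22 and 2927 with intervals apart, 2688 and 1479 after rescaling to a median of 0 over all genes, and 792 and 756 rescaled per part. Rescaled per part, 371 were higher and 398 lower at a pseudocount of 5, 490 higher at an FPKM minimum of 5, 198 and 249 at 2-fold, 78 and 170 with intervals apart, and 261 and 199 before the break alone.

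Of the lncRNA67 lists, 3 DNA replication and 17 mitotic genes were lower among members before the break alone, and 31 mitotic genes after rescaling over all genes. As deposited, the medians of p53 targets (−0.37), apoptosis regulators (−0.45), ribosomal proteins (−0.65) and known lncRNAs (−0.28) were reversed, which follows from the median of all genes (−0.64), and the estrogen response median was 0.14 before the break; the cause of the last was not tested. Of genes higher and lower in both knockdowns, 50 and 123 remained at 2-fold, 79 and 734 were found with lncRNA67 as deposited, and 93 and 87 before the break. The lncRNA median was 2.61 FPKM without single-exon loci, the protein-coding median 5.97 FPKM above 0 alone, and 49.3% of loci, counted in place of transcripts, were single-exon.

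Of all alternatives for list medians, 64 stayed alike and 7 moved with lncRNA152 knockdown, and with lncRNA67 knockdown 61 stayed alike, 38 moved and 5, those given above, reversed from a median outside the range of random lists. As deposited, 10 of 18 lncRNA67 medians changed sign, 6 of them from a median inside that range. For the numbers of mitotic and DNA replication genes that were lower, 8 stayed alike with lncRNA152, and 9 stayed alike and 3, given above, moved with lncRNA67 knockdown. For all other numbers of list members past 1.5-fold, 108 stayed alike and 26 moved with lncRNA152, and 115 and 81 with lncRNA67 knockdown.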

Other observations

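The 8 gene lists of this part were written after the data were seen, and the tests on translation factors and on GC content and length were written before their results.

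Beyond the cell-cycle lists, many genes of homologous recombination and most tubulins were lower with lncRNA152 knockdown. Of 23 genes of homologous recombination and the Fanconi anemia pathway, 19 were lower with lncRNA152 knockdown (median log2 −1.04) and 10 with lncRNA67 knockdown, rescaled (median −0.54), namely 2 of the 10 members before the break and 8 of the 13 after it. BRIP1, a helicase partner of BRCA1, was at 59.3 FPKM in the control and 13.5 FPKM in the lncRNA152 knockdown, RAD51 at 11.2 and 2.63 FPKM, and BRCA1 at 5.06 and 1.18 FPKM. Of 13 tubulins, 10 were lower with lncRNA152 knockdown (median −1.48), and 11 of 12 with lncRNA67 knockdown (median −1.04), TUBB at 587 and 164 FPKM in the lncRNA152 set, although near-identical tubulin genes share reads. Condensin, cohesin and chromatin genes (17 and 13 lower of 22, medians −1.06 and −0.65) and nuclear import and export genes (9 and 6 of 18, medians −0.60 and −0.42) had lower members too, in the lncRNA67 set all after the break. Proteasome genes had small negative medians (−0.43 and −0.26, below the random range) with 6 and 0 of 27 past 1.5-fold, while oxidative phosphorylation genes (1 and 0 lower of 33, medians −0.14 and −0.00) lay inside the range of random lists. The lncRNA67 values of all lists in this paragraph are rescaled. As deposited, the lncRNA67 medians were −1.26 for proteasome and −0.66 for oxidative phosphorylation genes.

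Lysosomal genes had medians above those of random lists in both knockdowns. Of 25 measured, 7 were higher and 1 lower with lncRNA152 knockdown (median log2 0.35), and 5 higher and 1 lower with lncRNA67 knockdown, rescaled (median 0.32, reversed to −0.43 as deposited), all 5 among the 15 after the break. The lipase LIPA was at 17.0 FPKM in the control and 34.9 FPKM in the lncRNA152 knockdown, the glucosidase GAA at 32.3 and 58.3 FPKM, the sulfatase GNS at 53.7 and 95.7 FPKM, and the protective protein CTSA at 128 and 212 FPKM. In the lncRNA67 set LIPA was at 17.5 FPKM in the control and 23.2 FPKM as deposited (25.3 rescaled).

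Ribosomal protein genes had medians above random lists in both knockdowns, in the lncRNA67 set after rescaling (0.39, reversed to −0.65 as deposited, though 0.18 as deposited before the break). The list medians lay 0.27 (lncRNA152) and 0.39 (lncRNA67) above those of random lists matched on expression, GC content and transcript length. This argues against GC content and length only as far as the broad bins of this matching go. Ribosomal protein mRNAs may lie at the edge of a bin, so a bias with length or abundance inside it is not excluded. A hypothesis is that mRNAs with a 5′ terminal oligopyrimidine sequence, which ribosomal protein mRNAs share, were affected together. Translation factors whose mRNAs carry that sequence had medians of 0.31 (random lists −0.23 to 0.14) and 0.41 (−0.13 to 0.21, but −0.54, the reverse, as deposited), although only 3 of 20 were past 1.5-fold in each set, with EEF2 at 1335 and 2103 FPKM (overlapping intervals) and EIF4B at 118 and 192 FPKM in the lncRNA152 set. This may reflect a larger share of such mRNAs in slower-dividing cells, since FPKM are relative to all transcripts, and no test here separates that from a direct effect.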
